A study of Homo sapiens with 6 samples.

How the data were processed

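CpG methylation was measured by whole-genome bisulfite sequencing in HEK293T cells, an established line derived from human embryonic kidney. Bisulfite turns unmethylated cytosine into uracil and leaves methylated cytosine as it is, so that a C in a read counts as a methylated call. Per the labels, 3 samples were treated with the solvent DMSO and 3 with BPK-25 at 30 µM, each for 48 h. The labels' protocol describes DNA sheared by sonication, an Illumina TruSeq library and sequencing on a HiSeq instrument with PhiX DNA added.

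The submitters' processing notes name FastQC 0.11.7, cutadapt 2.7, Bismark 0.22.3 and the genome build hg19. Trimming settings, alignment settings and any removal of PCR duplicates are not given in the sources used here. The authors deposited 1 table per treatment, in which the calls of replicates 1, 2 and 3 were summed, and the replicates are not given apart in it. Per the file headers, each row is the cytosine of a CpG on 1 strand, and the deposited columns used were the count of methylated reads, the read coverage (methylated plus unmethylated) and the methylation fraction. Every row had a coverage of at least 1 read, and the deposited fraction equalled methylated over total reads in every row of both tables to within 1e-05. The values are neither scaled nor corrected for depth.

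Both strands of a CpG were added to give 1 site, and sites on chromosomes 1 to 22 and X were used. The tables together held 27256402 such sites. DMSO had 167125267 calls, a mean of 6.13 per site, and covered 97.8% of the sites. BPK25 had 238354717 calls, a mean of 8.74 per site, and covered 99.0% of the sites, so that its depth was 1.43 times that of DMSO. At least 5 calls were present in both treatments at 15469423 sites. Levels are the percent of methylated calls with exact Clopper-Pearson 95% intervals, and differences are BPK25 minus DMSO in percentage points with Newcombe 95% intervals. These intervals treat each CpG call as independent, although several calls can come from the same read and reads carry no molecular identifiers. They cover counting error only, and are too narrow where calls go together.

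With 1 pooled table per treatment there is no spread between replicates. The planned permutation test across 3 and 3 samples, the quasi-binomial model and the edgeR alternative could therefore not be run, and the plan for pooled columns was followed. Genome-wide levels and levels by CpG density were given as values with intervals. Density was the number of CpG sites within 250 bp on either side of a site, itself included. Tiles of 5 kb with at least 10 sites and 50 calls in each treatment, and windows of 100 kb under the same minimums, were compared by a two-sided Fisher's exact test on pooled counts with Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of at least 10 points, and a window at an adjusted p under 0.05. Such a test compares the 2 pooled libraries, not the conditions, and it too treats calls as independent. As a measure of spread inside a library, the plus strand was compared with the minus strand of the same treatment in the same way. The tiles named are, by a rule set before the data were examined, the 10 with the largest loss and the 10 with the largest gain among those called.

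The main design and the first set of alternatives were fixed before the data were examined. These were a mean of site levels, coverage minimums of 5 and 10 per site or 20 and 100 per region, an upper limit of 10 times the median coverage, thinning to equal depth, removal of the genome-wide shift on the logit scale, other region sizes, a density distance of 100 bp, autosomes alone and a limit of 20 points. The density classes within 100 bp had lower limits on the number of sites. The genome-wide shift was estimated outside the 3 loci described next. Chosen after seeing the data were leaving out 3 loci of very high coverage, each strand alone, weighting every site by its DMSO calls, and a z test divided by the spread between strands. That last test used the mean squared z of strand comparisons in each decile of site number. Sites of high coverage had 50 or more calls in 1 treatment and over 5 times the depth-scaled coverage of the other. Such sites were joined into a segment across gaps of up to 2000 bp, and other sites could lie between them. A segment needed at least 3 sites of high coverage, and segments less than 200000 bp apart were joined into a locus. For the difference over all sites of a class, standard errors came from leaving out each of 23 chromosomes in turn. They describe the spread over the genome, not between cultures.

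The tile and window tests were tested on simulated data made from the real depths. Both libraries were drawn at the level of the summed DMSO and BPK25 calls of each region. Losses were given only to regions in a middle to high range of that level, so recovery outside this range was not measured. In the simulated 5 kb tiles, of 200 tiles given each loss, 43.0% were recovered at 15 points, 88.5% at 25 points and 100.0% at 40 points, with 13 unchanged tiles called among 558783 tested. In the simulated 100 kb windows, 25.5% were recovered at 2 points, 94.5% at 5 points and 100.0% at 10 points, with 13 unchanged windows called among 28461. Calls were drawn as independent, without the spread between strands of the real data. The simulated false calls therefore do not measure how many of the real calls are false.

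No hg19 sequence or annotation was used here, and the gene table at hand describes another build, whose coordinates cannot be set beside these. Planned comparisons of promoters, gene lists, genomic features and CTCF motif sites were therefore not run, and regions are given by hg19 coordinates, counted from 1. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, pyarrow 21.0.0 and matplotlib 3.10.9.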

Results

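The series asks about the NuRD complex, a nucleosome remodelling and histone deacetylase complex, at the sites bound by CTCF, a DNA-binding protein of chromatin loop anchors. BPK-25 is a small molecule known to bring about loss of NuRD proteins. The comparison made here was between HEK293T cells kept with BPK-25 and cells kept with the solvent DMSO, and the quantity was CpG methylation over the whole genome. Each treatment had 3 samples, whose calls the authors summed into 1 table, so that no value below has an error between replicates. DMSO was covered by a median of 6 calls per covered site and BPK25 by a median of 8.

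Methylation was slightly lower in BPK25 across the genome. Over all CpG sites, 59.86% of the calls in DMSO were methylated (95% interval 59.85 to 59.86) and 58.31% in BPK25 (58.30 to 58.32), a difference of -1.55 points (-1.56 to -1.54). Autosomes went from 61.03% to 59.50% and the X chromosome, which was far less methylated in this line, from 38.29% to 36.93%. The difference was -1.53 points on the plus strand and -1.56 points on the minus strand. Part of it came from 3 short loci with very high coverage in BPK25 alone, described further on. With these left out, a choice made after seeing the data, BPK25 stood at 58.53% and the difference was -1.33 points, with a standard error over chromosomes of 0.0539 points. Mitochondrial DNA, which serves as the background of unconverted cytosine, had 1.04% methylated calls in DMSO and 1.003% in BPK25. Without replicates apart it was not tested whether the genome-wide difference exceeds that between cultures.

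The lower level was seen where CpG sites are sparse and at intermediate density. Where they are densest, the direction depended on how the calls were counted and weighted. Sites with under 5 CpG sites within 250 bp went from 52.31% to 50.82% (-1.49 points), those with 5 to 9 from 63.32% to 61.71% (-1.61 points), and those with 10 to 19 from 69.71% to 68.14% (-1.57 points). At 20 to 39 sites the levels were 54.31% and 53.62% (-0.693 points). In the densest class, 40 or more sites, which takes in CpG islands, DMSO had 23.81% and BPK25 23.87%, a difference of 0.0585 points (0.00235 to 0.115). On the X chromosome this class went from 42.87% to 44.63% (1.76 points, 1.38 to 2.13), a difference that was not run with sites weighted by their DMSO calls. A minimum of 10 calls per site, with the 3 loci still in, moved the genome-wide difference to -2.52 points. It moved the class with 10 to 19 sites to -3.84 points and the densest class to -41.0 points. With a minimum of 5, leaving the loci out changed these 2 classes from -2.07 and -5.45 to -1.59 and 1.85 points. A minimum of 10 was not run without the loci. The 2 densest classes changed sign with the calls counted. With the 3 loci left out they stood at 0.201 and 1.49 points, and with every site given its DMSO weight as well they stood at -0.869 and -0.192 points. The ratio of BPK25 to DMSO coverage fell from 1.48 in the sparsest class to 1.32 in the densest.

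**Figure D1:**
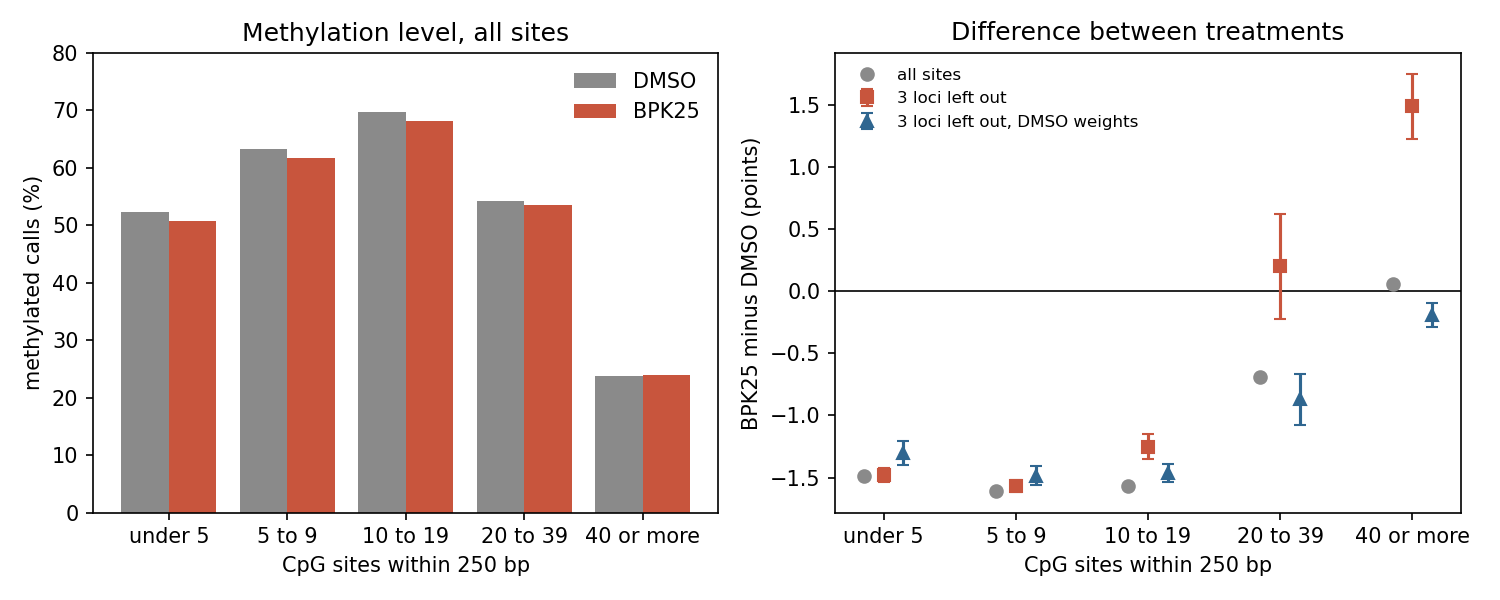
Left, percent of methylated calls in DMSO (grey bars) and BPK25 (red bars) by number of CpG sites within 250 bp. Right, BPK25 minus DMSO in percentage points over all sites (grey circles), with 3 loci left out (red squares) and with each site also weighted by its DMSO calls (blue triangles); bars are 2 standard errors over 23 chromosomes, and the densest class moves from 1.49 to -0.192 points between the last 2.

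Tiles with intermediate and high levels were lower in BPK25 by a similar share of their level. Tiles of 1 kb were put into classes by their level on a single strand and measured on the other, so that the class and the value shared no calls. On the autosomes, BPK25 had between 0.975 and 0.986 times the DMSO level in each of the 9 classes from 10% to 95%, lower by between 1.42% and 2.47% of the level. On the X chromosome the same 9 classes gave ratios from 0.975 to 0.985. Autosomal tiles at 80 to 90% went from 83.06% to 81.23%, and those at 20 to 30% from 27.51% to 27.04%. The difference was smaller again in the top class, 95 to 100%, at -1.37 points on the autosomes and -1.23 points on the X chromosome. In the lowest class, 0 to 5%, the X chromosome differed by -0.0969 points over all such tiles, and by 0.652 points (0.279 to 1.02) in its tiles with more than 40 CpG sites per kb. The autosomes differed by 0.0736 points over all such tiles, but by -0.184 points (-0.235 to -0.133) in tiles with 3 to 5 CpG sites per kb and by 0.0117 points (-0.00768 to 0.0312) in those with more than 40. Autosomal tiles with more than 40 CpG sites per kb and intermediate levels differed less or the other way, by 0.692 points (0.511 to 0.874) at 20 to 30%, 0.134 points (-0.105 to 0.373) at 50 to 60% and -0.234 points (-0.425 to -0.0424) at 60 to 70%. Those on the X chromosome differed by 1.79 points (1.16 to 2.42) at 20 to 30% and -1.26 points (-1.97 to -0.548) at 60 to 70%. In these dense tiles each treatment kept its own calls as weights, and values at DMSO weights were not run. The BPK25 to DMSO coverage ratio of the autosomal ones was 1.23 at 0 to 5% and 1.34 at 60 to 70%, so that a shift of calls between sites could move these differences. Autosomal tiles of that density at 70 to 100% went from 84.07% to 82.67%. On the X chromosome they went from 78.68% to 78.44% (-0.243 points, -0.666 to 0.180).

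All 23 chromosomes were lower in BPK25, with and without the 3 loci. Chromosomes 2 and 6 stood apart over all sites, at -2.79 and -2.87 points. With the loci left out they were at -1.43 and -1.26 points, and the 23 chromosomes then ranged from -1.50 points on chromosome 9 to -0.862 points on chromosome 10, with a median of -1.34 points. Chromosome 10 stood at -1.34 points with sites above 10 times the median coverage left out.

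**Figure D2:**
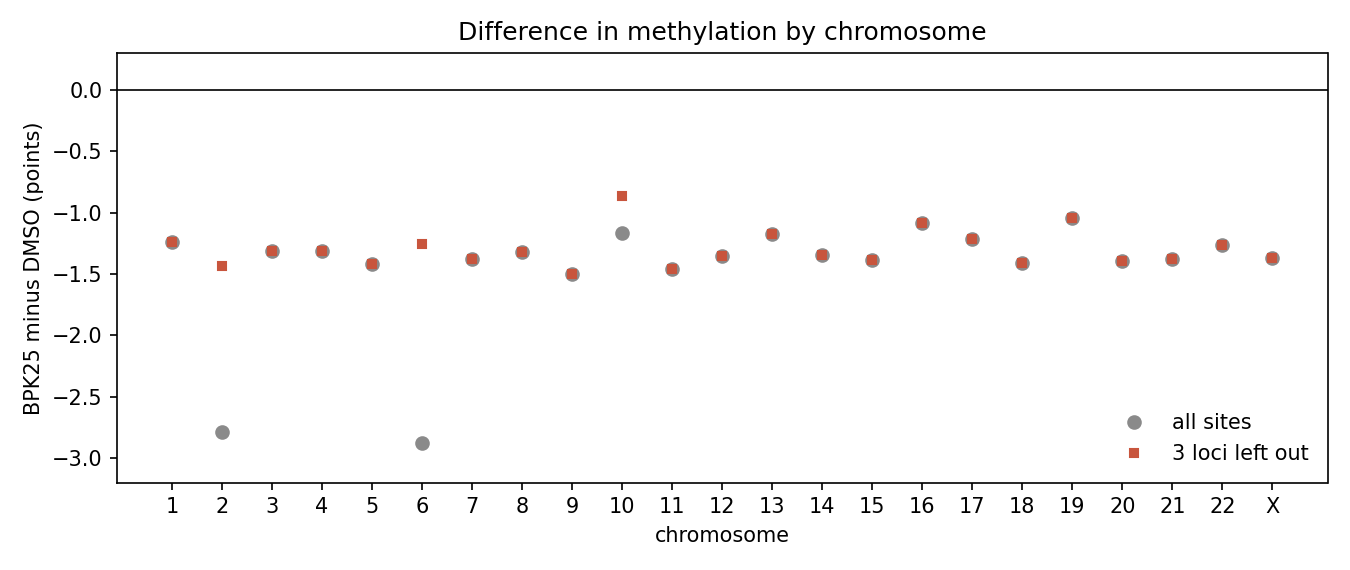
BPK25 minus DMSO in percentage points for each chromosome, over all sites (grey circles) and with the 3 loci left out (red squares). All points lie below 0, and chromosomes 2 and 6 move from -2.79 and -2.87 points to -1.43 and -1.26 points.

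The large-scale pattern of methylation was alike in both treatments. Across 28461 windows of 100 kb, the levels of both treatments had a Pearson correlation of 0.995; windows are not independent replicates. Under 60% in DMSO, the limit set for partially methylated domains, were 11038 windows (38.8%). These went from 40.34% to 39.14% over their summed calls, with the 3 loci still in. The 17423 windows at 60% or more, summed in the same way, went from 69.86% to 68.42%. The median differences of the 2 groups were -0.781 and -1.45 points, with 72.6% and 84.4% of their windows lower in BPK25. Over all windows, the median differed by -1.19 points, with quartiles at -2.09 and -0.234 points, and 79.8% of the windows were lower in BPK25. Fisher's exact test with Benjamini-Hochberg adjustment called 7635 windows lower and 639 higher, on a median of 5086 calls per window in DMSO and 7309 in BPK25. With the genome-wide shift removed, 1311 windows were lower and 1815 higher, so that the share of higher windows among those called went from 7.72% to 58.1%. The same shift was applied to every window, although the difference varied with level, so that the correction itself can make part of this change. The minus strand minus the plus strand of the same treatment gave medians of 0.0259 points in DMSO and -0.00275 points in BPK25, but still called 3397 and 3127 windows. Scaled by that spread between strands, the test called 9 windows lower and 1 higher, of which 5 lay in the 3 loci and 5 elsewhere.

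**Figure D3:**
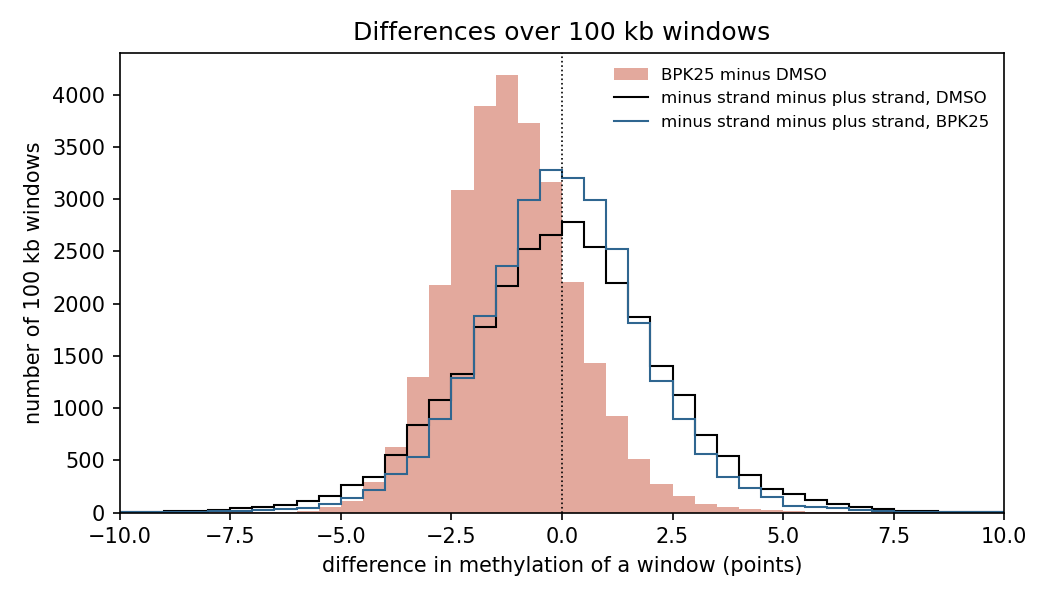
Number of 100 kb windows by difference in methylation in percentage points, for BPK25 minus DMSO (red area) and for the minus strand minus the plus strand inside DMSO (black line) and inside BPK25 (blue line). The treatment distribution is centred at -1.19 points, and the strand distributions are centred near 0.

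At the scale of 5 kb, 558783 tiles could be tested, on a median of 248 calls in DMSO and 359 in BPK25. The median tile differed by -1.34 points. Tiles at 80% or more made up 14.3% of the tiles in DMSO and 10.0% in BPK25, and tiles under 10% made up 2.82% in each. These shares were not computed at equal depth, and fewer calls per tile spread the levels more widely in DMSO. Fisher's exact test called 4341 tiles lower and 1921 higher, which is 1.12% of those tested. With the genome-wide shift removed, 2124 were lower and 2874 higher, so that higher tiles went from 30.7% to 57.5% of the calls. The same logit shift, 0.0551, was applied to every tile, although the fall varied with level and CpG density. Part of this change can therefore come from the correction itself. Higher tiles were rich in CpG, with a median of 110 sites against 38 in all tested tiles. Their coverage after depth had a median of 0.885 times that of DMSO, against 1.01 in all tested tiles. Over all sites, the coverage ratio was also lower in the denser CpG classes, so this is not particular to the higher tiles. Lower tiles had a median of 57 sites and 0.977 times the coverage.

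Strands of the same library differed in more tiles than the treatments did. Plus against minus strand called 9691 tiles in DMSO and 10960 in BPK25, where no treatment differs. Of 4417 tiles called lower on the plus strand alone, with a median of -16.7 points, the median on the minus strand was -1.27 points, close to that of all tiles. For 2548 tiles called higher on the plus strand, the medians were 16.8 and 0.00429 points. Some tiles did recur: 201 were called higher on each strand taken alone, against 12.3 for independent calls, and 172 lower, 13 of them in the 3 loci, against 37.4. The numbers for independent calls take all tiles as equally likely to be called, while called tiles were richer in CpG. An overlap above them therefore does not by itself show a difference between treatments. Of the tiles called higher on the plus strand, 50.04% were higher on the minus strand, against 40.9% of all tiles. Of those called lower on the plus strand, 57.1% were lower on the minus strand, against 59.0% of all tiles. Scaled by the spread between strands, the test called 23 tiles lower and 5 higher, of which 13 lay in the 3 loci and 15 elsewhere.

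The named losses were dominated by the high-coverage loci. Of the 10 tiles with the largest loss, 9 lay at chromosome 10, between 70330001 and 70455000, or at chromosome 2, between 74275001 and 74320000. The tile at chromosome 10, 70450001 to 70455000, had 74.8% methylated calls in DMSO and 3.22% in BPK25 (-71.6 points, -75.7 to -66.9), but 7.46 calls per site in DMSO against 346.2 in BPK25. The tile at chromosome 2, 74275001 to 74280000, went from 56.6% to 2.94% with 8.52 and 344.2 calls per site. With sites above 10 times the median coverage left out, the difference was -4.53 points in the first of these tiles and -1.76 points in the second (adjusted p 0.743 and 0.896 by Fisher's exact test). Of the 9 tiles, the ones still called were at chromosome 10, 70330001 to 70335000, with -17.3 points, and at chromosome 2, 74315001 to 74320000, with -19.2 points. The limit in BPK25 was 80 calls per site, while the flanks had 6.86 on chromosome 2 and 6.65 on chromosome 10. Sites with extra calls could therefore stay in, so these differences do not show a loss beyond the excess coverage. The loss outside these loci was at chromosome 6, 32145001 to 32150000, from 49.2% to 11.9% on 59 and 126 calls, it was not lower on each strand taken alone, and its adjusted p scaled by the spread between strands was 0.0682.

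Among the 10 named gains, the best covered lay at chromosome 19, 6500001 to 6505000, and at chromosome 10, 64130001 to 64135000. The first went from 39.4% on 654 calls to 67.6% on 592 calls (28.1 points, 22.7 to 33.3), and the second from 14.3% on 594 calls to 42.7% on 363 calls (28.4 points, 22.5 to 34.1). Their adjusted p was 6.48e-19 and 9.82e-18 by Fisher's exact test, and 0.0355 and 0.0433 when scaled by the spread between strands. Coverage after depth was 0.635 and 0.428 times that of DMSO in these tiles. The tile at chromosome 7, 126985001 to 126990000, went from 27.4% to 62.6% with a coverage of 0.676 times that of DMSO, and its scaled adjusted p was 0.0691. The largest gain, at chromosome 15, 28750001 to 28755000, was 51.6 points (34.9 to 63.9) on 50 and 87 calls, with a scaled adjusted p of 0.0670. The other 6 gains, on chromosomes 6, 9, 21, 22 and X, had scaled adjusted p between 0.275 and 0.945. The tile on chromosome 22 was not higher on each strand taken alone.

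The 3 loci with excess coverage were at chromosome 2, 74213557 to 74329293, at chromosome 6, 74229774 to 74230958, and at chromosome 10, 70332108 to 70451547. The first held 4 separate segments with 5353 bp in all, the second was a single segment of 1185 bp, and the third held 5 segments with 5114 bp in all. Calls per site in the segments were 2300 in BPK25 and 18.1 in DMSO on chromosome 2, 4199 and 32.9 on chromosome 6, and 802.2 and 11.8 on chromosome 10. In BPK25 these calls were 0.886%, 0.664% and 2.12% methylated. No segment met the same rule in the other direction.

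**Figure D4:**
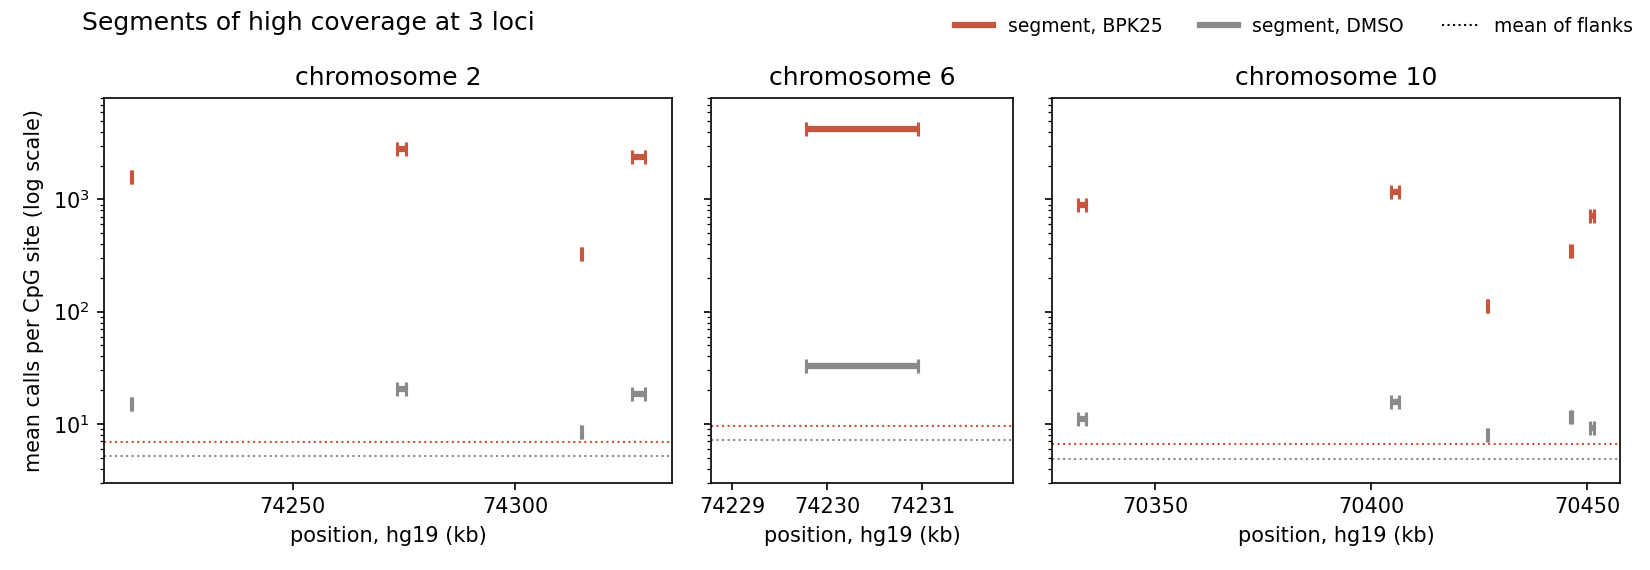
Mean calls per CpG site (log scale) in each segment of high coverage at the 3 loci, by hg19 position in kb, in BPK25 (red) and DMSO (grey); dotted lines give the mean of the flanking 50000 bp on each side. BPK25 reaches 4199 calls per site on chromosome 6, against 32.9 in DMSO.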

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

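All tests in this part were chosen after the result was seen. Read coverage, which weights the levels but is not the measured outcome, was far above that of the DMSO control at 3 loci in BPK25. After correction for depth it was 89.3-fold that of DMSO on chromosome 2, 89.6-fold on chromosome 6 and 47.5-fold on chromosome 10. Whether the cells' own DNA also changed in methylation there was not tested. A copy number gain of the chromosome 2 and 10 regions would raise the sequence between their segments, but the BPK25 to DMSO coverage ratio there was at most 1.44, against 1.43 over the genome; the chromosome 6 locus is a single segment, where a flank ratio of 1.32 leaves a gain of the segment itself open. Extra unmethylated copies of the chromosome 2 and 10 segments are a candidate explanation, since with the cells' own share taken out the extra calls there were methylated at 1.23% at most, and whether such copies were in the library or in the cells stays open. From general knowledge of hg19, not checked here against an annotation, the chromosome 10 and 2 intervals lie in TET1 and TET3, genes of 5-methylcytosine dioxygenases, and the chromosome 6 interval at the start of EEF1A1, whose promoter is used in expression vectors.

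DMSO also had an excess at the 3 loci, of 0.562%, 0.611% and 0.818% of the excess calls in BPK25. The loci held 919862 calls in BPK25 and 24221 in DMSO.

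The second pattern is the slightly lower level over the genome in BPK25. The calls from the 3 loci are not its whole cause, since -1.33 points remain outside them. Leaving out the loci removes those calls only. It does not test whether extra copies, if they were in the cells, affected methylation elsewhere. Less complete conversion in DMSO would need mitochondrial DNA to differ by -3.31 points, and the measured difference was -0.0336 points (-0.0606 to -0.00668). A loss of methylated calls in proportion to the level, as filled-in fragment ends or overconversion might give, cannot be told apart from lower methylation: the unplaced contig gl000220 differed by -0.0128 points where -1.18 would follow, but sites of very high depth elsewhere differed by -0.621 points where -0.825 would follow. The treatment stays open and untested, since each treatment is 1 pooled table.

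The third pattern is the higher level of the densest CpG class, 1.49 points once the 3 loci were left out, with 23 of 23 chromosomes higher. A gain at the same sites would persist when every site keeps its DMSO weight, but the difference then was -0.192 points with a standard error of 0.05003. A shift of calls towards methylated CpG-dense sites in BPK25 is consistent with that value. In tiles with more than 40 CpG sites per kb, the coverage ratio was 1.23 where levels were 0 to 10% and 1.36 where they were 70 to 100%, while in tiles with 3 to 5 sites per kb it was 1.51 and 1.49. Why unmethylated dense DNA gave fewer calls in BPK25 than the depth ratio of 1.43 would give was not tested.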

How the results depend on the processing

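Leaving out the 3 loci, using each strand alone, weighting sites by their DMSO calls and scaling by the spread between strands were chosen after seeing the data; the other settings were planned. No paired analysis was possible because the deposited columns give the 3 replicates of a treatment as 1 sum and carry no replicate number. For the same reason leaving out each replicate, the second test, the edgeR fit and other splits of the samples were not run. Promoter, gene list, genomic feature and CTCF motif results, with all their alternatives, were not run. The cause of a change was not tested unless said.

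The genome-wide fall and that of the 3 sparser density classes kept their direction under all settings run. Values are in points, genome-wide first and then from the sparsest to the densest class. The mean of site levels gave -1.41, -1.31, -1.50, -1.53, -1.05 and -0.193. With the 3 loci still in, a coverage minimum of 5 gave -2.0002, -1.53, -1.70, -2.07, -2.54 and -5.45, and a minimum of 10 gave -2.52, -1.36, -1.65, -3.84, -3.23 and -41.0. Without the loci, a minimum of 5 gave -1.71, -1.53, -1.65, -1.59, -1.03 and 1.85, and a minimum of 10 was not run. An upper limit on coverage gave -1.39, -1.48, -1.59, -1.34, 0.343 and 1.47. Leaving out the loci gave -1.33, -1.48, -1.57, -1.25, 0.201 and 1.49, with the mean of site levels as well -1.41, -1.31, -1.50, -1.53, -1.05 and -0.193, and with DMSO weights as well -1.35, -1.30, -1.49, -1.46, -0.869 and -0.192. The plus strand gave -1.53, -1.49, -1.59, -1.55, -0.779 and 0.209, and the minus strand -1.56, -1.49, -1.62, -1.58, -0.613 and -0.0909. Autosomes alone gave -1.52 genome-wide. Density within 100 bp, with lower limits on the number of sites, gave -1.52, -1.62, -1.53, -1.12 and -0.0321 for its own classes.

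The median window stayed between -1.20 and -1.18 points except with the genome-wide shift removed, which by construction left -0.0169. That setting gave 1311 lower and 1815 higher windows and 2124 lower tiles. Windows of 1 Mb, of which there are fewer, gave 2482 lower and 5 higher. The plus strand gave 4361 lower windows and the minus strand 4272. Scaled by the spread between strands, 9 windows were lower and 1 higher, and 23 tiles lower and 5 higher. A limit of 20 points left 244 lower and 142 higher tiles. Depth thinned to the lower of both libraries gave 3113 lower and 1570 higher tiles, and 1 kb tiles 5274 and 2492. Of 105 values available for the 20 named tiles under other settings, 87 stayed called, 18 did not and 0 changed sign. Values on a strand alone are missing from these for several tiles of low coverage. Among those are chromosome 6, 32145001 to 32150000, and chromosome 22, 16180001 to 16185000, whose strands did not share the same direction. Of 46 chromosome values under 2 settings, 46 were below 0. At this depth, losses of 15 points were recovered in 43.0% of simulated tiles, with calls drawn as independent.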

Other observations

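All values in this part were looked at after the main results. Long stretches of low methylation were chosen on the calls of both treatments together, so that a stretch with a large gain would not be among them. Runs of at least 5 kb in which every 1 kb tile was under 15% numbered 1861, of which 234 lay on the X chromosome, and were 5.19% methylated in DMSO and 5.23% in BPK25 (0.0409 points, -0.0175 to 0.0992). Of these, 950 were lower and 909 higher in BPK25. The longest, 23 kb at chromosome 7, 57282001 to 57305000, had 5.76% in DMSO and 6.54% in BPK25. A run of 19 kb at chromosome 1, 2614001 to 2633000, had 1.94% and 1.59%.

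The X chromosome of HEK293T was the least methylated of the 23 chromosomes examined, and its 100 kb windows had a median of 34.2% in DMSO and 32.9% in BPK25, against 64.7% and 63.6% on the autosomes. Its densest CpG class stood the other way round, at 42.9% in DMSO on the X and 23.2% on the autosomes.

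The unplaced contig gl000220 was at 53.11% in DMSO and 53.09% in BPK25, on 185.1 and 259.7 calls per site. Another 67 unplaced, unlocalised and haplotype contigs were at 37.54% and 37.01% together.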
